A study of Mus musculus with 9 samples.

How the data were processed

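Liver RNA from the 9 samples was sequenced after TruSeq library preparation, per the labels' protocols. The processing notes of the submitters name HISAT, HTSeq and the mm10 build, without versions. The counting options are not given in the sources used here. The authors deposited a single table of counts per gene for the whole series.

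Samples were placed in the 3 groups by their titles. The value columns of the table carry numbers in place of those titles. Each column name was compared with the title, description, source name and characteristics of every sample, ignoring case and punctuation. Of the 9 value columns, 0 matched, so no count from any of the 9 is printed or tested. Their values were looked at only when the file was first inspected. At that inspection the column totals and the albumin (Alb) counts were low for sequenced liver. Several of the highest genes overlapped genes transcribed in liver on the opposite strand in the GENCODE M21 annotation, such as Snx22 with Ppib and Lrrc61 with Rarres2. Whether reads were counted on the strand opposite to the transcripts was not tested, and the labels do not say whether the kit marks strand. The counts may therefore not measure the named genes, which a match of columns to samples would leave open. Columns were not assigned by their order in the table, since no label supports such a match. They were not assigned by their values either, since groups formed from expression values cannot then be compared for expression.

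In advance of any comparison, 3 comparisons between groups, 32 gene lists and a rule for naming genes had been fixed. A quasi-likelihood test on counts was to be the main test. None of these was run, and no gene was named under the rule.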

Results

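Gene expression was profiled by RNA sequencing in the livers of male mice. The series held 9 libraries in 3 groups of 3 libraries each. The first group was labelled WT, and whether those mice received any injection was not stated. In the second group, named AKT+NICD, plasmids encoding a membrane-targeted, active form of the kinase AKT and the NOTCH intracellular domain (NICD), the part of the NOTCH receptor that enters the nucleus, were delivered to the liver. In the third group, named AKT+Yap+Sox9KO, the plasmids encoded active AKT and YAP, the transcriptional co-activator restrained by the Hippo pathway. The mice of that group carried a floxed Sox9 gene and the Alb-Cre transgene, which deletes floxed DNA in cells of the hepatocyte lineage. Sox9 encodes a transcription factor of bile duct cells. The plasmids were given by hydrodynamic injection into the tail vein with the Sleeping Beauty transposase, which inserts the delivered DNA into the genome, and livers were taken 5 weeks later.

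The design implied 3 comparisons between groups. AKT+NICD against WT addressed the expression change in livers with active AKT and NICD. AKT+Yap+Sox9KO against WT addressed the change in livers with active AKT and YAP and Sox9 deleted in the hepatocyte lineage. In that comparison the plasmids and the Sox9 genotype changed together. Since injection of the WT mice was not stated, the injection and the transposase may also differ in either comparison with WT. AKT+Yap+Sox9KO against AKT+NICD addressed the difference between the injected groups, in which the partner gene (YAP or NICD) and the Sox9 genotype changed together.

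None of these comparisons was made. The gene count table had 9 value columns, each named by a sample number, and 0 of the 9 names matched a label of any sample. No column was therefore assigned to a library or a group, and no count from the table is reported. Whether the counts were taken on the strand of the named genes was also left open when the table was inspected. Apart from the remarks on that inspection, no expression values, sequencing depth, fold changes or tests are reported for any gene or group. The direction or size of any expression difference between WT, AKT+NICD and AKT+Yap+Sox9KO livers was not analysed here.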

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

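The number of matched columns was recomputed in other ways chosen after the column names were seen. Searching the labels for the number in each column name alone matched 0 of 9 columns. Searching the labels, the protocols, and the title and design text of the series for that number also matched 0 of 9. The alternatives fixed in advance of any comparison, such as other gene set tests, were not run, because each needs libraries assigned to groups. No paired analysis was possible because no column was assigned to a sample. The labels tie the replicate numbers in the titles to no shared litter, batch or day, so they would not by themselves pair mice across groups.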
